A study of Homo sapiens with 4 samples.

How the data were processed

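MeRIP-seq was performed on A549 cells and on the cisplatin-resistant line A549/DDP. Per the labels' protocols, RNA fragments carrying m6A were enriched with an antibody, and the enriched and the input RNA of each line were made into libraries with a stranded mRNA kit. Reads were aligned with HISAT2 and the build was hg19, per the submitters' processing notes. The peak caller, its threshold, how libraries were scaled and the annotation release are not given in the sources used here. The authors deposited 1 list of peaks per cell line, with 33465 rows for A549/DDP and 28601 for A549, and each list was taken as made from the immunoprecipitated and the input library of that line, which the files do not state. Per the file headers, a row gives a peak's position, its exon blocks, a transcript identifier, a gene name, the strand, the transcript length and the transcript regions the peak touches. The fold enrichment is a linear ratio as the authors' caller gave it, deposited per peak. The p-value of a peak is likewise the authors' deposited value. It was at most 0.00676 in A549/DDP and 0.00646 in A549, was listed as 0 in 244 and 175 rows, and whether it was adjusted is not stated. The lists hold no read counts, so the depth of the libraries is unknown, and neither the expression of a gene nor the height of a peak can be compared between the lines. Many peaks share the authors' values: the most frequent pair in the A549/DDP list (fold 15.2, p = 0.000324) occurred at 160 positions in 109 genes, and that in the A549 list (fold 12.4, p = 0.000955) at 203 positions in 134 genes.

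Rows with the same position, strand and blocks on several transcripts were counted as 1 distinct peak. Peaks remained redundant where isoforms gave overlapping peaks with other blocks, and overlapping peaks of a list were therefore also merged into regions. Gene symbols were brought to current names through a table of human genes of GRCh38.p14, from which no coordinate was used. Of 7957 symbols, 7829 matched that table, 7294 of them as the current symbol. Genes are printed with the symbol of the lists. Positions are printed counting from 1.

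A peak was called shared if it overlapped a peak of the other list by at least 1 exonic base on the same strand. Chance overlap was measured by shifting one list along each chromosome 100 times and by placing peaks at random within their transcripts 20 times, the latter over rows of peak and transcript and not over distinct peaks. A gene was listed for a line if any peak carried its symbol. The transcript region of a peak was taken from the lists. Shares are given with exact binomial 95% intervals, which cover counting error only. For 20 gene lists the number of genes with a peak in one line alone was placed among 10000 random lists of the same size, drawn from all genes with a peak and matched on the decile of the gene's highest fold. The percentile counts ties as lying equally on both sides. A list stood apart if a percentile lay below 2.5 or above 97.5.

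The gene lists covered m6A writers, erasers and readers, platinum and drug transport, NRF2 with glutathione and metallothionein, nucleotide excision repair, homologous recombination with Fanconi anaemia, mismatch repair with translesion synthesis, p53 targets, apoptosis, epithelial-mesenchymal transition, Hippo, Wnt with Notch and Hedgehog, receptor tyrosine kinase with MAPK and PI3K, cell cycle, autophagy with endoplasmic reticulum stress, stemness with aldehyde dehydrogenase, lung epithelium, markers of other cell types, chromatin regulators, cytosolic ribosomal proteins and the respiratory chain. Lists, comparisons and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes with the highest fold at a peak stronger than the median p of its list among genes of A549/DDP alone, the same for A549 alone, and the 10 genes listed in both whose worse rank by that fold was best. From each gene list it took up to 4 genes per line alone and up to 3 in both by the same fold, and all m6A writers, erasers and readers. Other members of the gene lists named in the text, and the genes without a peak, were named after their values were seen.

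The alternatives were other rules for overlap, folds of at least 5 or 2, an equal number of peaks with the 13659 strongest of each list by p, which does not equalise depth, merged regions, other sets of chromosomes, strand ignored and random lists without matching. Where both lists were cut by strength, a gene listed in one line alone could still have a weaker peak in the other list. The overlap code was checked on simulated data made from the A549 list, in which 1950 of 3250 regions were kept in place: 1950 were called shared and 0 wrongly. The others were moved to contigs of their own, so this set-up held no partial overlaps. Overlapping bases were also counted directly for 300 by 300 real peaks, with 0 wrong pairs. For random lists, 11 of 200 simulated lists of 30 among 6000 genes without enrichment fell outside the 2.5 to 97.5 range and 190 of 200 lists with 4-fold odds lay above it. The simulated genes were independent and had no peak strength. This checked the code and does not show how the percentiles behave where absence goes with p or genes share peaks. Sequence motifs under peaks were not analysed here, and some members of the gene lists are not reported by name. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.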

Results

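N6-methyladenosine (m6A), the most abundant internal modification of messenger RNA, was mapped by MeRIP-seq in a cisplatin-sensitive and a cisplatin-resistant line of lung adenocarcinoma cells. In this assay fragmented RNA is pulled down with an antibody against m6A and sequenced beside the untreated fragments (input), and a peak is a stretch of transcript with more reads in the pull-down than in the input. A549 is an established human lung adenocarcinoma line, and A549/DDP is its cisplatin-resistant counterpart according to the labels (DDP is an abbreviation of cisplatin, a platinum drug that crosslinks DNA). The data comprised 4 libraries, 1 immunoprecipitated and 1 input library per cell line, and were analysed as 1 peak list per cell line. With 1 library per group no difference between the lines had a replicate check and no significance test between the lines was made, so that every comparison describes these libraries. The lists carried no read counts and the depth of the libraries was unknown. Fold enrichments and p-values of peaks are the authors' own values, and were used to describe, rank and filter peaks within a list. Where folds of a gene are given for both lines, each is the highest at a peak stronger than its list's median p. Such folds can belong to different sites of the gene. Positions are on hg19. Intervals are exact binomial (Clopper-Pearson) 95% intervals that cover counting error only, and are too narrow because peaks on overlapping isoforms of a gene are not independent.

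The first comparison asked how many m6A peaks each line carried and where the strongest lay. A549/DDP had 32069 distinct peaks in 7026 genes and A549 had 27319 in 6450 genes, a ratio of 1.17. After overlapping peaks of a list were merged, 12441 and 10733 regions remained, a ratio of 1.16. The median fold enrichment was 3.81 in A549/DDP (quartiles 2.59 and 6.26) and 3.72 in A549 (quartiles 2.53 and 6.33), and the median peak covered 211 and 210 exonic bases. The gene that ranked highest by fold in both lists was AES (now TLE5), a corepressor of the Groucho family. Its strongest peak had a fold of 558 in A549/DDP (chromosome 19, 3061222 to 3062555, 5′ UTR and coding) and of 480 in A549 (3062228 to 3062555, 5′ UTR). PCBP1, which encodes a poly(rC)-binding protein, followed with folds of 231 and 123 at its start codon (chromosome 2, 70314615 to 70315148 in A549/DDP and to 70315177 in A549). DAZAP1 (chromosome 19, folds 70.4 and 108) and the G protein subunit gene GNB2 (chromosome 7, 100271402 to 100274979, folds 50.4 and 63.6) also had their peak of highest fold across the 5′ UTR and the coding sequence in each list, although the DAZAP1 peak of smallest p in A549/DDP lay in the 3′ UTR (fold 5.80). ARHGAP1, a GTPase-activating protein gene, had its peak in the 3′ UTR (chromosome 11, folds 68.0 and 109), and C12orf65 (now MTRFR) and ZFPM1 had theirs across the stop codon. The histone methyltransferase gene SETD1A had a coding peak (chromosome 16, 30990874 to 30992082 in A549/DDP, fold 86.2, and 30990844 to 30991911 in A549, fold 58.6). The last of these 10 genes were the mitochondrially encoded MT-ND2 (folds 127 and 57.4) and MT-ATP8 (folds 46.1 and 67.1). The MT-ND2 peak covered 983 bases in A549/DDP and 953 in A549, and MT-ATP8 overlaps MT-ATP6, so its peak cannot be assigned to one of them.

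The second comparison asked how far the m6A peaks of the sensitive and the resistant line coincided. Of the A549/DDP peaks, 21536 (67.2%, 66.6 to 67.7) overlapped an A549 peak by at least 1 exonic base on the same strand, and of the A549 peaks 21302 (78.0%, 77.5 to 78.5) overlapped an A549/DDP peak. Among the strongest 10% of peaks by p these shares were 98.7% and 97.9%, and among the weakest 10% 29.6% and 48.0%. Lists shifted along their chromosomes overlapped by 0.381% and 0.420% on average over 100 shifts. Within the 16184 transcripts that had peaks in both lists, where a peak counts once for each transcript it is listed on (26762 and 24957 rows), 80.3% of A549/DDP rows and 86.4% of A549 rows were shared, against 39.7% and 42.1% for peaks placed at random in the same transcripts. Peaks at which the lists coincided included the 3′ UTR peak of the nucleotide excision repair gene GTF2H5 (chromosome 6, 158613225 to 158613554 in both lists), the 3′ UTR peak of LPCAT1 (chromosome 5, 1461538 to 1462194 in both) and the stop codon peak of RPS6 (chromosome 9, 19376214 to 19378419 in both). The peaks that were not shared numbered 10533 in A549/DDP and 6017 in A549, and 56.1% and 59.0% of them lay in a gene that had another peak in the other list. With an equal number of peaks, the 13659 strongest of each list, the shares were 74.1% and 74.7%.

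The third comparison asked which genes carried m6A peaks in one line and not in the other. A peak was listed in both lines for 5524 of 7952 genes (69.5%, 68.4 to 70.5), in A549/DDP alone for 1502 (18.9%, 18.0 to 19.8) and in A549 alone for 926 (11.6%, 10.9 to 12.4). The excess of A549/DDP genes turned round with the 13659 strongest peaks of each list, where 765 genes had a peak in A549/DDP alone, 885 in A549 alone and 3030 in both. There a gene listed in one line alone could have a weaker peak in the other list. The excess stayed at a fold of at least 5 (1556 and 1014 genes) and at a fold of at least 2 (1563 and 956). Genes listed in one line mostly had weak peaks: their median smallest p was 4.07e-05 in A549/DDP and 6.68e-05 in A549, against 3.98e-19 for genes listed in both. A gene can lack a peak in a list because its transcript was scarce there, and the lists do not separate this from loss of the modification.

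Among genes listed for A549/DDP alone, the highest folds at peaks stronger than the list's median p belonged to PAX2, a developmental transcription factor gene, and JPH3, which encodes a junctophilin. PAX2 had 8 peaks, the strongest in the 3′ UTR with a fold of 55.1 (chromosome 10, 102587400 to 102588116). JPH3 had 3, the strongest by fold across the stop codon with a fold of 48.1 (chromosome 16, 87723343 to 87730444). SRSF3, a splicing factor gene, had a fold of 39.9 across the 5′ UTR and coding sequence (chromosome 6, 36562145 to 36564573). ODC1, the rate-limiting enzyme of polyamine synthesis, had a fold of 38.7 in the 5′ UTR (chromosome 2, 10585357 to 10588481). The adaptor gene NCK2 and the profilin gene PFN2 (both 35.2) and the formin gene FMN2 (30.5) also had their strongest peak at the 5′ UTR, so that it did in 5 of these 10 genes. The others were ZNF211 (35.2, 3′ UTR), C19orf26 (now CBARP, 34.0, coding) and KIAA1919 (now SLC60A2, 32.8, stop codon). KIAA1919 had the same fold and the same authors' p as a peak of the unrelated gene FOXA1 in this list. Without read counts it is unknown how far such high folds rest on few input reads.

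Among genes listed for A549 alone, PAQR7, which encodes a membrane progestin receptor, had a fold of 48.7 (chromosome 1, 26188001 to 26188480). STOM, the stomatin gene, had 48.3 (chromosome 9, 124102696 to 124103113), and ESYT2, an extended synaptotagmin gene, had 38.0 (chromosome 7, 158523686 to 158524285). These peaks lay in the 3′ UTR, as did those of SBNO1 (29.7), ANKS4B (28.9), PNPT1 (28.1), COMMD2 (26.4) and MSMO1, a gene of cholesterol synthesis (28.9). CYB5D2 had its peak in the 5′ UTR (fold 24.8). Here too, COMMD2 had the same fold and authors' p as a peak of SLX4, and MSMO1 as a peak of SMAD7. HSPA1A, an inducible heat shock protein gene, had a fold of 42.1 in its coding sequence, but this peak lay on an alternate haplotype contig and the gene has a near-identical copy, HSPA1B, so its assignment is uncertain. The share of genes absent from the other list went from 0.285% (0.0345 to 1.03) in the strongest 10% of A549/DDP genes to 58.2% in the weakest, and among A549 genes from 2.17% (1.19 to 3.62), with 2.02% in the next class, to 40.9%.

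**Figure D1:**
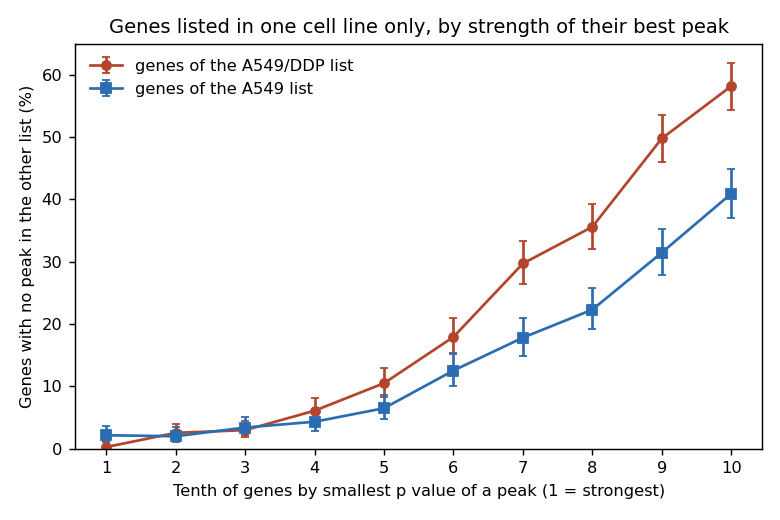
Percentage of the genes of each peak list that had no peak in the other list, in 10 classes of genes ranked by the smallest p-value of any of their peaks (1 is the strongest class), with exact binomial 95% intervals as error bars. The curves end at 58.2% for A549/DDP genes and 40.9% for A549 genes in the weakest class.

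The fourth comparison asked where along the transcript the peaks lay. Peaks touching a 5′ UTR made up 13.6% of A549/DDP peaks (13.3 to 14.0) and 8.42% of A549 peaks (8.09 to 8.75), a difference of 5.21 percentage points and a ratio of 1.62. Peaks touching a 3′ UTR were less frequent in A549/DDP (50.4%, 49.9 to 51.0) than in A549 (56.0%, 55.4 to 56.5), and the shares touching coding sequence were 65.2% and 64.5%. Among peaks with a fold of at least 5 the 5′ UTR shares were 21.5% and 11.4%. Among peaks that were not shared 17.5% and 5.10% touched a 5′ UTR, and among shared peaks, which lie close together in the lists by definition, 11.7% and 9.36%. The 3′ UTR shares were 36.5% and 53.6% among peaks that were not shared and 57.2% and 56.6% among shared peaks, so the direction was not the same in both sets. Of the 5524 genes with peaks in both lists, 596 had a 5′ UTR peak in A549/DDP alone, 112 in A549 alone and 798 in both. Genes chosen by the naming rule with peaks in both lists and a 5′ UTR peak in A549/DDP alone were SETD1A, ZFPM1, SLC31A1, LRRC8A, JAG2, MKI67, NDUFB10 and YTHDF1, and the one with a 5′ UTR peak in A549 alone was SOX4. The strongest SOX4 peak in A549 ran from the 5′ UTR to the 3′ UTR (3171 bases, chromosome 6, 21594301 to 21597471). It covered the site of the strongest SOX4 peak in A549/DDP, in the 3′ UTR (21596753 to 21597352). The 5′ UTR peak of JAG2, a Notch ligand gene, had a fold of 31.7 in A549/DDP (chromosome 14, 105634921 to 105635101).

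**Figure D2:**
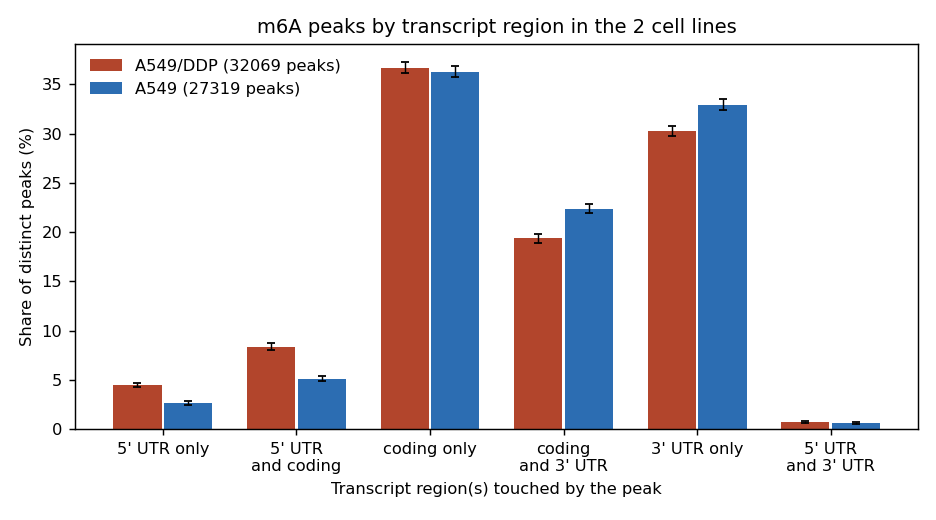
Percentage of the distinct peaks of each list by the transcript regions they touch, with exact binomial 95% intervals; the last group also covers the coding sequence between both UTRs. Bars for the 5′ UTR alone or with coding sequence are higher in A549/DDP (4.50% and 8.39%) than in A549 (2.63% and 5.14%), and bars for the 3′ UTR alone or with coding sequence are lower (30.3% and 19.4% against 32.9% and 22.4%).

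The fifth comparison took 20 gene lists fixed before the data were examined, and set the number of their genes listed in one line alone against 10000 random lists of the same size matched on the decile of highest fold. Of the 40 percentiles so obtained, 2 would lie below 2.5 or above 97.5 by chance alone. 4 lists had a percentile there: NRF2 and glutathione genes, homologous recombination genes, chromatin regulators and cytosolic ribosomal proteins. A percentile describes these libraries and is not a test of the cell lines. The matching did not cover p, with which absence from the other list went more closely than with fold. In A549/DDP, peaks not shared and shared peaks had median folds of 3.63 and 3.91, but median authors' p of 7.76e-05 and 2.51e-12. A list rich in genes with weak peaks can therefore reach a high percentile for that reason.

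The m6A writers, erasers and readers had a peak in either line for 20 of 26 members, 14 of them in both. The methyltransferase complex genes METTL14, WTAP, ZC3H13, RBM15, CBLL1 and KIAA1429 (now VIRMA), the methyltransferase gene METTL16, both demethylase genes ALKBH5 and FTO, the readers YTHDF1, YTHDF2 and HNRNPA2B1, and HNRNPC and RBMX had peaks in both. Some were weak: the only METTL14 peak in A549 had a fold of 2.55 (the authors' p = 0.00339). In A549 the peaks of WTAP, RBM15, CBLL1, KIAA1429 and YTHDF1 were also all weaker than the list's median p. The same held in A549/DDP for METTL14, FTO and YTHDF1. The ALKBH5 peak lay in the coding sequence (chromosome 17, 18087583 to 18088001 in A549/DDP, fold 47.2, and 18087613 to 18087911 in A549, fold 18.6). FTO had 3′ UTR peaks (chromosome 16, smallest p 3.55e-05 in A549/DDP and 6.03e-10 in A549). ELAVL1, IGF2BP2, METTL3, METTL5 and YTHDF3 had a peak in A549/DDP alone. ELAVL1 had a fold of 12.9 across its 5′ UTR and coding sequence (chromosome 19, 8056590 to 8070492), YTHDF3 had 5.12 there (chromosome 8, 64099006 to 64099305), and IGF2BP2 had 15 peaks, the strongest by p in its 3′ UTR (chromosome 3, 185362180 to 185362508, fold 3.02). METTL3, the catalytic subunit, had 1 weak coding peak (chromosome 14, 21971479 to 21971598, fold 2.12, the authors' p = 0.000112). IGF2BP1 had a peak in A549 alone, in the 3′ UTR with a fold of 1.88 (chromosome 17, 47126867 to 47127167). FMR1, IGF2BP3, PRRC2A, RBM15B, YTHDC1 and YTHDC2 had no listed peak. The count of 5 A549/DDP genes lay at percentile 78.6 of random lists, and at 98.4 with the 13659 strongest peaks of each list, where 6 members had a peak in A549/DDP alone.

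Genes of platinum and drug transport had a peak for 9 of 22 members, 8 in both lines. These included the copper transporter gene SLC31A1, a route of cisplatin uptake, with a 3′ UTR peak (chromosome 9, 116023252 to 116023461 in A549/DDP, fold 7.04, and to 116023699 in A549, fold 10.5), and the efflux pump gene ABCC1 (chromosome 16, folds 8.95 and 7.11 at its 3′ end). LRRC8A, a subunit of the volume-regulated anion channel, had folds of 3.80 and 6.11. ABCC5 had a peak in A549/DDP alone (the authors' p = 0.000603) and 0 members had one in A549 alone, at percentiles 29.1 and 14.2. With the strongest peaks of each list 0 and 2 members were so listed (20.2 and 82.9). The copper ATPase genes ATP7A and ATP7B, ABCB1, ABCC2 and ABCG2 had no listed peak.

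NRF2 target, glutathione and metallothionein genes had a peak in A549 alone for 6 members and in A549/DDP alone for 1, with 18 in both. The 1 A549/DDP gene lay at percentile 1.01 of random lists, and at 10.6 with the strongest peaks of each list. The 6 A549 genes, at percentile 90.8 (55.2 with the strongest peaks, 5 genes), included the aldo-keto reductase genes AKR1B10, AKR1C1 and AKR1C2, the glutathione peroxidase gene GPX2 and the heme oxygenase gene HMOX1. AKR1B10 had a fold of 11.6 in its 5′ UTR (chromosome 7, 134212344 to 134212584) and GPX2 had 2.49 at its 3′ end (chromosome 14, 65405876 to 65406505, the authors' p = 1e-179). AKR1C1 and AKR1C2 are close paralogs with weak peaks, so their assignment is uncertain. The A549/DDP gene was TXN, the thioredoxin gene, with a 5′ UTR peak (fold 4.52). NFE2L2, which encodes NRF2 itself, had its strongest peaks by fold across the 5′ UTR and coding sequence in both lines (chromosome 2, folds 27.0 and 17.3), and SRXN1 (15.8 and 19.0) and NQO1 (7.72 and 8.79) had peaks in both.

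Stemness and aldehyde dehydrogenase genes had a peak in A549 alone for 4 members and in A549/DDP alone for 2 (percentiles 89.7 and 26.5, and 93.2 and 9.79 with the strongest peaks, 4 and 0 genes). ALDH3A1, an aldehyde dehydrogenase gene, had 19 peaks in A549, the strongest across its stop codon with a p listed as 0 (chromosome 17, 19641297 to 19641680, fold 3.57), and none in A549/DDP. The transcription factor gene KLF5 (fold 3.67) and ALDH2 (1.91) were also listed in A549 alone, with KLF4, while ALDH1A3 and BMI1 were listed in A549/DDP alone. SOX4 (folds 19.9 and 42.1), MYC (9.74 and 11.1) and ALDH7A1 (3.99 and 3.58) had peaks in both lines.

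Homologous recombination and Fanconi anaemia genes had a peak in A549/DDP alone for 11 members and in A549 alone for 1, with 11 in both. The A549/DDP count lay at percentile 99.9 against a mean of 4.61 in random lists. These 11 included BRCA2, BRIP1, FANCC, FANCE, NBN, PALB2, RAD52, RBBP8, TP53BP1 and XRCC3, and all except TP53BP1 were named after their values were seen. TP53BP1, a chromatin reader at DNA breaks, had 14 peaks with a fold of 4.69 (chromosome 15, 43714277 to 43724491, coding). The other 10 had only peaks weaker than the median p of the list, and with the 13659 strongest peaks of each list 3 members were listed for A549/DDP alone, at percentile 88.1. The A549 gene was CHEK1. BRCA1 had 3′ UTR peaks in both lines (chromosome 17, 41196823 to 41197273 in A549/DDP, fold 7.71, and to 41197123 in A549, fold 22.3), and SLX4 and H2AFX (now H2AX) had peaks across their stop codons in both.

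Nucleotide excision repair genes, which remove platinum adducts from DNA, mostly had peaks in both lines (18 of the 21 with a peak). XPA had a coding peak in A549/DDP alone (chromosome 9, 100437752 to 100449407, fold 2.91), at percentile 4.94 for the count, and RPA2 and UVSSA had a peak in A549 alone (38.5). The RPA2 and UVSSA peaks were all weaker than the median p of the list. With the 13659 strongest peaks of each list the counts turned to 5 in A549/DDP alone and 0 in A549 alone, at percentiles 93.0 and 3.44. At most 1 of these 5 lacked any listed A549 peak, since over all peaks XPA was the only member in A549/DDP alone. GTF2H5 (folds 7.04 and 9.91), XRCC1 (7.04 and 9.09) and ERCC5 (9.77 and 5.86) had peaks in both. Of 10 mismatch repair and translesion synthesis genes with a peak, 8 had it in both, among them MSH6 (folds 6.30 and 2.45), and 2, among them MSH3, had one in A549/DDP alone (percentile 48.0, and 15.2 for the A549 count of 0). The strongest peaks of each list gave 2 and 1, at percentiles 94.4 and 61.1. The MSH6 folds belong to different coding sites. At its overlapping peaks of smallest p the MSH6 folds were 4.03 and 2.33 (chromosome 2, 48027901 to 48030644 in A549/DDP and to 48028290 in A549).

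Of p53 targets and DNA damage response genes, 14 had peaks in both lines, 3 in A549/DDP alone (BTG2, EDA2R and PMAIP1) and 1 in A549 alone (ZMAT3), at percentiles 53.4 and 27.5, or 56.6 and 7.17 with the strongest peaks (2 and 0 genes). BTG2, EDA2R, PMAIP1 and ZMAT3 had only peaks weaker than the median p of their list. Apoptosis regulators were listed in both for 19 members, in A549/DDP alone for 8 and in A549 alone for 1 (BID), at percentiles 91.5 and 13.0. These counts were 2 and 3 with the strongest peaks of each list, at percentiles 41.8 and 63.2. The A549/DDP gene with a peak stronger than the median was BIRC3, an inhibitor of apoptosis (fold 2.76, chromosome 11, 102201870 to 102206773, coding). The proapoptotic gene BAX had its strongest peaks at its 3′ end in both lines (chromosome 19, 49464406 to 49465025 in A549/DDP, fold 17.1, and 49464141 to 49465055 in A549, fold 58.9). BBC3, which encodes PUMA (25.2 and 7.60), CFLAR (30.5 and 5.37), GADD45A (13.4 and 19.4) and GADD45B (10.7 and 9.09) were also listed in both. The BBC3 peak covered 1541 exonic bases in A549/DDP and 330 in A549. The CFLAR folds belong to different 3′ UTR sites. At its overlapping peaks of smallest p the CFLAR folds were 8.01 and 5.37 (chromosome 2, 202031949 to 202032368 in A549/DDP and 202032009 to 202032248 in A549).

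Epithelial-mesenchymal transition genes were divided, with 12 in both lines, 5 in A549/DDP alone (CLDN1, ITGB1, MMP9, TWIST1 and ZEB2) and 6 in A549 alone (CDH1, FN1, MMP14, SMAD4, SNAI1 and TGFBR1), at percentiles 57.7 and 95.4. Among these single-line genes only ITGB1 and CDH1 had a peak stronger than the median p of its list. The order of the counts reversed with the strongest peaks of each list, to 3 and 1, at percentiles 80.4 and 12.5. CDH1, the E-cadherin gene, had a peak across its stop codon in A549 (chromosome 16, 68867292 to 68867532, fold 4.25), and ITGB1, an integrin gene, had a coding peak in A549/DDP (chromosome 10, 33200840 to 33201048, fold 1.77). SMAD7 (folds 34.0 and 28.9), TGFB1 (23.2 and 31.0) and SMAD3 (6.47 and 5.58) had peaks in both. The TGFB1 folds belong to different sites, the 3′ end in A549/DDP and the 5′ UTR in A549. At its overlapping 3′ end peaks the TGFB1 folds were 23.2 and 23.4 (chromosome 19, 41836764 to 41838038 in A549/DDP and to 41837061 in A549). Lung epithelium genes had a peak for 8 of 27 members, 6 in both, including FOXA1 (32.8 and 22.3), FOXA2 (12.3 and 7.08) and LPCAT1 (4.48 and 5.45). The mucin gene MUC5B was listed in A549 alone with 16 peaks (fold 21.5, chromosome 11, 1271560 to 1272639) and CAV1 in A549/DDP alone (percentiles 59.0 and 39.9). Over the strongest peaks of each list 3 members were listed in A549 alone and 0 in A549/DDP alone, at percentiles 95.9 and 18.2. Markers of other cell types, fixed to look for foreign cells, had a peak for 4 of 29 members: CD68, COL1A1 and CHGA in both lines and CD14 in A549 alone (percentiles 27.3 for A549/DDP and 81.1 for A549, and 33.7 and 97.2 with the strongest peaks, where 0 and 2 were listed in one line).

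Hippo pathway genes had peaks in both lines for 18 members, in A549/DDP alone for CTGF (now CCN2), TEAD1 and TEAD2 and in A549 alone for VGLL4, at percentiles 36.7 and 19.5. TEAD1, TEAD2 and VGLL4 had only peaks weaker than the median p of their list. With the 13659 strongest peaks of each list the A549/DDP count of 5 lay at percentile 97.6. CTGF, a target of YAP, had a fold of 6.33 across its 5′ UTR and coding sequence (chromosome 6, 132272129 to 132272513). YAP1 had its peak at the start codon in both lines (chromosome 11, 101981270 to 101981779 in A549/DDP, fold 17.8, and 101981252 to 101981611 in A549, fold 13.4), as had AJUBA (15.2 and 9.32), and NF2 had 3′ UTR peaks (37.5 and 19.4). Wnt, Notch and Hedgehog genes had peaks in both for 19 members, in A549/DDP alone for 5 (FZD6, LRP6, PTCH1, SUFU and TCF7L1) and in A549 alone for 5 (FZD5, JAG1, NOTCH1, NOTCH3 and RNF43), at percentiles 58.7 and 94.6. Among these single-line genes only FZD6, FZD5, JAG1 and NOTCH3 had a peak stronger than the median p of its list. The A549 count was 8, at percentile 99.8, with the strongest peaks of each list. The receptor gene NOTCH3 had a fold of 6.70 (chromosome 19, 15271938 to 15272327, coding), its ligand JAG1 had 6.13 (chromosome 20, 10620068 to 10620457, stop codon) and FZD5 had 6.61 in A549, while FZD6 had 9.22 in A549/DDP (chromosome 8, 104342061 to 104343606). FZD2 (31.7 and 20.1), JAG2 (31.7 and 13.7) and GSK3B (12.5 and 30.6) had peaks in both. The JAG2 folds belong to different sites, the 5′ UTR in A549/DDP and the 3′ end in A549. Its 3′ UTR peak of smallest p had the same position in both lists, with folds of 6.80 and 6.25 (chromosome 14, 105608038 to 105608666).

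Receptor tyrosine kinase, MAPK and PI3K genes had peaks in both lines for 21 members, in A549/DDP alone for 4, among them ERBB3, INSR and NF1, and in A549 alone for 2, among them DUSP4, at percentiles 33.6 and 36.6, which became 92.8 and 56.8 with the strongest peaks of each list (6 and 4 genes). The 4 genes in A549/DDP alone over all peaks had only peaks weaker than the median p of the list. DUSP4, a MAPK phosphatase gene, had a fold of 3.68 across its stop codon (chromosome 8, 29194056 to 29195972, the authors' p = 2.51e-48). HRAS (22.3 and 17.6), RPTOR (12.5 and 18.0) and IRS1 (7.82 and 8.74) had peaks in both. Cell cycle genes were listed in both for 19 members, in A549/DDP alone for 6 (BUB1B, CCNE1, CDK6, PLK1, RB1 and WEE1) and in A549 alone for CCNA2 and CCNE2, at percentiles 54.6 and 17.2, and with the strongest peaks of each list 2 and 5 were listed in one line, at percentiles 37.7 and 82.3. None of the 8 genes listed over all peaks in one line had a peak stronger than the median p, whereas CDK4 (16.4 and 33.5), FOXM1 (4.28 and 3.81) and MKI67 (4.20 and 4.84) had such peaks in both. Autophagy and endoplasmic reticulum stress genes had 17 members in both, 5 in A549/DDP alone (ATG14, ATG3, ATG5, DNAJB9 and EIF2AK3) and 4 in A549 alone (ATG13, ATG7, BECN1 and ERN1), at percentiles 52.5 and 68.2. They were 1 and 4 with the strongest peaks of each list, at percentiles 12.4 and 74.0. Of the autophagy and stress genes listed over all peaks in one line, only ATG3 had a peak stronger than the median p. ATG2A (6.77 and 9.36), WIPI2 (6.99 and 6.12) and DDIT3 (7.25 and 5.92) had peaks in both, and ATG3 had a fold of 2.29 in A549/DDP.

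Histone and chromatin regulators had peaks in both lines for 28 of 41 members, in A549/DDP alone for 7 (ARID2, CHD1, DNMT3A, EED, KDM4A, TET2 and TET3) and in A549 alone for 0. The latter count lay at percentile 0.885 against a mean of 3.76 in random lists, and at 3.57 with the strongest peaks of each list, while the former lay at 64.7. None of the 7 genes had a peak stronger than the median p of the list. The Polycomb-associated gene ASXL1 (91.5 and 28.1) and ARID1A (66.9 and 20.7), a subunit of a chromatin remodelling complex, had their strongest peaks by fold across the 5′ UTR and coding sequence in both lines. Cytosolic ribosomal protein genes had peaks in both for 42 of 71 members, in A549/DDP alone for 6 (percentile 1.10) and in A549 alone for 5 (percentile 5.69). These percentiles became 7.61 and 32.7 with unmatched random lists, and 2.68 and 0.0900 with the strongest peaks (4 and 5 genes). RPS12 had a peak in A549/DDP across its stop codon with the authors' p = 1e-254 (chromosome 6, 133138170 to 133138703, fold 2.71), RPL23 and RPL7 had folds of 5.98 and 4.86 there at the 5′ end, and RPL35 (1.56) and RPS23 (1.65) were listed in A549 alone. Ribosomal protein genes have many processed pseudogenes, so these assignments are uncertain. Respiratory chain genes had peaks in both for 15 members, in A549/DDP alone for 2, among them NDUFA5, and in A549 alone for NDUFA10, NDUFA4, NDUFS4, NDUFV2 and UQCRC1, at percentiles 3.48 and 66.5. These became 12.6 and 93.0 with unmatched random lists, and 10.2 and 79.0 with the strongest peaks (1 and 7 genes). NDUFA4 had a fold of 2.85 in the 3′ UTR (chromosome 7, 10973047 to 10973227), and NDUFS7 (21.1 and 23.7), COX6B1 (4.67 and 3.04) and NDUFB10 (2.98 and 2.53) had peaks in both. The NDUFS7 folds belong to different sites. Its A549/DDP peak of smallest p, which reached the A549 site, had a fold of 16 (chromosome 19, 1393316 to 1395583).

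**Figure D3:**
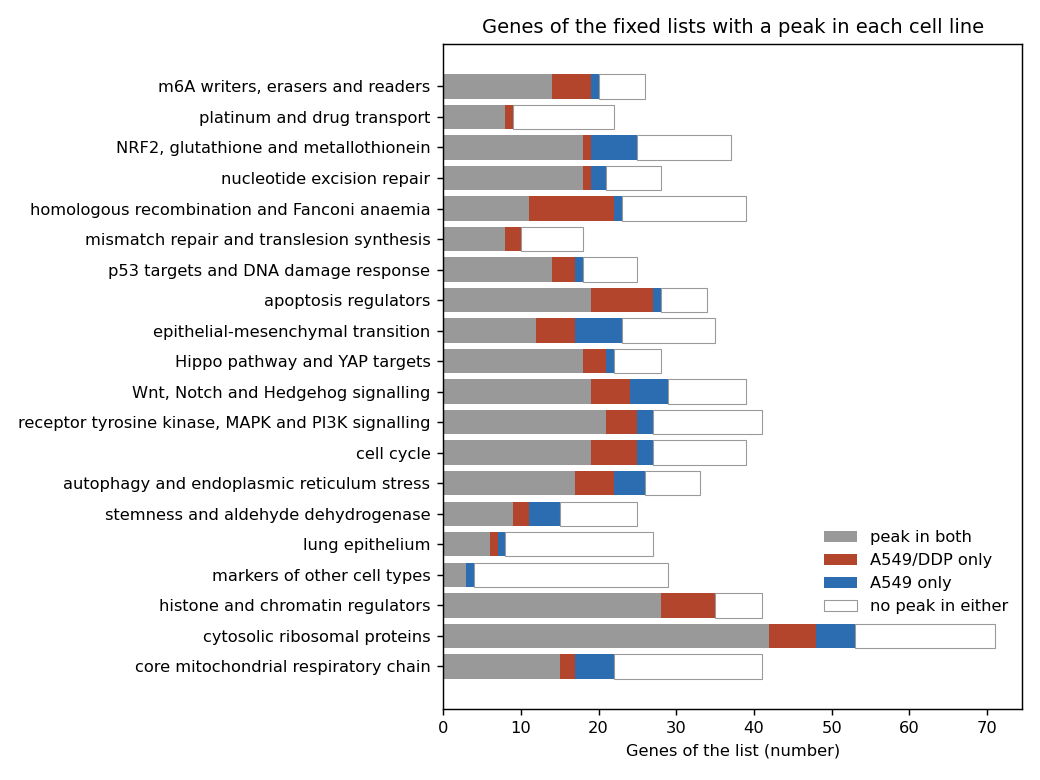
Number of genes of each fixed list with a peak in both cell lines, in A549/DDP alone, in A549 alone and in neither. The homologous recombination list has 11 genes in A549/DDP alone and 1 in A549 alone, and the NRF2 list has 1 and 6.

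The last comparisons concerned chromosomes and peaks per gene. Chromosome 13 held 1.05% of A549/DDP peaks (0.942 to 1.17) and 0.772% of A549 peaks (0.672 to 0.883), a ratio of shares of 1.36, with 43 genes listed for A549/DDP alone and 9 for A549 alone. With the 13659 strongest peaks of each list its ratio was 1.20, below those of chromosomes 21 (1.33), 6 (1.32), 3 (1.30) and 10 (1.26). Chromosome 3 held 5.67% (5.42 to 5.93) and 4.77% (4.52 to 5.03), a ratio of 1.19, with 106 and 37 such genes. The lowest ratios were 0.885 for chromosome 11 and 0.886 for chromosome 7, and with the strongest peaks 0.832 for chromosome 7 and 0.852 for chromosome 22. Genes with a peak had a mean of 4.57 distinct peaks in A549/DDP and 4.24 in A549, with a median of 3 in each, and 1.79 and 1.68 merged regions.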

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

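Fold of at least 2, merged regions for shares and for peaks per gene, the whole span of a peak, the equal number of peaks and the genes in both lists for UTR shares, and all tests of gene families were chosen after seeing the data. Values are given for A549/DDP and then A549. No paired analysis was possible because each group held 1 library, and no library could be left out. DRACH motifs (in 100 bases, in the whole peak, or as GGAC) and the region at the middle of a peak in a reference annotation were not run, since no genome or annotation of hg19 was used here. The cause of the changes below was not tested, apart from smaller sets giving smaller counts by construction. The 5′ UTR share stayed higher and the 3′ UTR share lower in A549/DDP under every alternative below. The excess of genes listed in A549/DDP alone did not: it was 576 genes over all peaks and turned to -120 with the 13659 strongest peaks per list (765 genes in A549/DDP alone and 3030 in both). It was 542 genes at a fold of at least 5 and 607 at a fold of at least 2. With single-line genes limited to those with a peak above their list's median fold it was 420. Unknown depth limits what absence from a list means.

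At a fold of at least 5 there were 11204 and 9253 peaks, 51.0% and 59.7% shared, 2458 genes in both, 2.79 and 2.67 peaks per gene, 5′ UTR shares of 21.5% and 11.4% (difference 10.1 points) and 3′ UTR shares of 48.8% and 58.6% (-9.81). Merging left 12441 and 10733 regions, 63.9% and 74.2% shared, 1.79 and 1.68 per gene, with 14.8% and 9.74% in 5′ UTRs and 59.2% and 65.1% in 3′ UTRs. With the strongest peaks 74.1% and 74.7% were shared, 14.6% and 9.11% lay in 5′ UTRs and 57.6% and 65.7% in 3′ UTRs (-8.19). At a fold of at least 2, 65.0% and 76.1% were shared, and 14.8% and 9.03% lay in 5′ UTRs. In genes with peaks in both lists the 3′ UTR shares were 51.8% and 55.3% (-3.46). Sharing was 64.8% and 75.6% when 50% of the shorter peak had to overlap, 50.6% and 59.3% when 50% of both had to, 68.7% and 79.7% within 100 bases, and 69.2% and 80.6% for peaks with a fold above their list's median against the whole other list. Genes with such a peak numbered 986 in A549/DDP alone and 566 in A549 alone. The other 30 values stayed within the interval of a share, 1 point of a difference or 1.5 times a count. They include the excesses of 542, 607 and 420 genes.

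With the strongest peaks of each list, 3 gene lists that stood apart came inside the central range (NRF2, homologous recombination and chromatin), the m6A, Hippo and Wnt lists came outside it, and the ribosomal list stayed outside by its A549 count. This setting also changes which genes enter the random lists. The ratio of peak shares moved to 1.20, 1.30, 1.07 and 0.832 for chromosomes 13, 3, 18 and 7. Of gene families, the ankyrin repeat genes turned from percentile 2.03 to 79.0 for A549 alone.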

Other observations

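The tests on genes listed in one line and on protocadherins, the rankings by p and the gene families were chosen after the result was seen. The tests on the 5′ UTR were chosen after the data were examined but before their own values were seen. Ratios of 5′ UTR shares by transcript length were not among those tests. Ranked by the authors' p, the strongest genes listed in A549 alone were the aldehyde dehydrogenase gene ALDH3A1 (p listed as 0, fold 3.57), the aldo-keto reductase gene AKR1B10 (p = 1e-242, fold 1.72), the calcium-binding protein gene S100P (p = 1e-214, fold 3.82), CPLX2 (p = 1e-208, fold 2.91), TNS4 (p = 1e-182, fold 12.8), the glutathione peroxidase gene GPX2 (p = 1e-179, fold 2.49) and UNC13D (p = 1e-170, fold 10.7). The TNS4 peak covered 2243 exonic bases at the 3′ end of the gene (chromosome 17, 38632080 to 38638387), and the S100P peak spanned the transcript (chromosome 4, 6695628 to 6698896). By the authors' p in A549/DDP alone they were RPS12 (p = 1e-254, fold 2.71), the homeobox gene HOXD11 (p = 6.31e-77, fold 8.71, chromosome 2, 176972700 to 176974394), RPL23 (p = 1.58e-61, fold 5.98), SNRPF (p = 2.51e-54, fold 4.65) and NAP1L1 (p = 3.16e-54, fold 2.44). THBS1, the thrombospondin-1 gene, had a 3′ UTR peak there (the authors' p = 6.31e-50, fold 4.03, chromosome 15, 39887690 to 39888318).

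Grouped by symbol, 221 zinc finger genes (ZNF) had a peak, 59 in A549/DDP alone and 20 in A549 alone, the former at percentile 99.99 of matched random lists (mean 36.8). Solute carrier genes (SLC) went the other way, with 19 in A549/DDP alone and 27 in A549 alone of 129, the latter at percentile 99.7. Centrosomal CEP genes had 9 and 1 of 23 (percentile 98.9 for A549/DDP). With the 13659 strongest peaks of each list all 3 came inside the central range, at 76.8 for ZNF (15 genes in A549/DDP alone, 19 in A549 alone), 67.7 for SLC and 89.4 for CEP. The other families tried were ankyrin repeat genes and clustered protocadherins, and HOX, claudin, keratin and TRIM genes. The last 4 lay inside the central range over all peaks, while with the strongest peaks HOX genes lay at 98.2 for A549 alone.

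The 5′ UTR share of peaks was 5.21 points higher in A549/DDP than in A549. Weak extra calls and a different set of genes were argued against as the whole cause, since the difference was 5.51 points among the 13659 strongest peaks of each list and 4.67 points in genes with peaks in both. In the shortest of 3 classes of transcripts the difference was 8.72 points. Points cannot be compared between the classes, since the A549 share itself fell from 13.5% in the shortest to 4.30% in the longest. The ratios were 1.65, 1.60 and 1.76 from the shortest to the longest class, without a steady rise. Ratios were not part of the test fixed beforehand and carry no interval, and the highest was in the longest class. They therefore cannot decide on a 3′ bias of the A549 libraries that grows with transcript length, which stays open. A loss of 5′ ends at any length, or lower input coverage at 5′ ends in A549/DDP, stays open without reads, as does m6Am next to the cap, which the antibody can also bind. A biological difference between the lines, with more modification near the start of transcripts in resistant cells, may also account for it and was not tested.

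Genes listed in one line alone may simply have had a peak just under the caller's threshold in the other. For A549/DDP genes this stays open, since 0.285% of the strongest 10% were absent from the A549 list (interval 0.0345 to 1.03) and the absence grew as peaks weakened. Of the strongest 10% of A549 genes, 2.17% (14 of 645, interval 1.19 to 3.62) were absent from the A549/DDP list. This was above a limit of 1% for a threshold effect, but the limit was chosen after the result was seen. The next class lay above it in both lines, with 2.56% of A549/DDP genes (1.52 to 4.02) and 2.02% of A549 genes (1.08 to 3.42) absent. The limit therefore does not set the lines apart, the contrast rests on 1 class, and the explanation stays open for both lines. The 14 strong A549 genes include ALDH3A1, AKR1B10 and GPX2, for which a lower transcript level in A549/DDP, a lower level of m6A or a different isoform could each give the same lists. No expression values were used here to separate them.

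All 21 clustered protocadherin genes with a peak were listed in A549/DDP alone. The peaks of all 21 lay in 2 regions shared between genes of the gamma cluster (chromosome 5, 140890986 to 140891149 and 140892396 to 140892546), and 0 genes had a region of their own, so that exons common to the cluster are a likely source of the count and the 21 genes stand for 2 sites. None remained among the 13659 strongest peaks of each list.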
